A study of Mus musculus with 20 samples.

How the data were processed

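RNA from whole fetal mouse hearts was measured on 20 Affymetrix MG-U74Av2 arrays: 8 controls (corn oil) and 4 at each of 1.5, 3 and 6 µg/kg TCDD, given on gestation day 14.5 with collection on day 17.5. For 1 array at 1.5 µg/kg the label writes the treatment day in a form that was not used; the other 19 give day 14.5. Per the labels, total RNA was extracted with Trizol, double-stranded cDNA was made with the Superscript Choice kit, and biotinylated cRNA was made with an ENZO kit. The authors deposited MAS5 signal, a linear intensity per probe set; the MAS5 version was not given. A 2% trimmed mean between 500.28 and 500.341 in every array shows that they had scaled the arrays alike.

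The table holds 12488 probe sets, of which 66 AFFX controls were left out of the comparisons. Each array was scaled to a trimmed mean of 500 and values were taken as log2(signal + 32). Probe sets were kept where at least 4 arrays lay at or above their own 40th percentile, which left 8097 of 12422. Gene symbols came from the platform annotation. Of all probe sets 10833 carry 1 symbol, 396 carry several and 1193 carry none; 10817 were found in the RefSeq table of assembly GRCm38.p6, which gave gene locations. The locations of the probes themselves were not used. The kept probe sets stand for 6099 genes, 1052 of them with more than 1 probe set.

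Linear models were fitted in R 4.3.3 with limma 3.58.1 (lmFit, contrasts.fit, and eBayes with an intensity trend), with all 20 arrays in 1 fit. Tests were two-sided and p was adjusted by Benjamini-Hochberg within each comparison, with a threshold of 0.05. The comparisons were each dose against controls, the doses against each other, a joint F test of the 3 doses, a linear trend over dose in µg/kg, and controls 1 to 4 against controls 5 to 8. Of 34 gene lists fixed in advance, 32 had at least 5 measured genes and were tested with limma's camera at a preset correlation of 0.01, on the brightest probe set of each gene. Camera with an estimated correlation and fry were run beside it. Fry asks whether the genes of a list move on balance in 1 direction, and does not compare them with other genes. Scores per array are means of log2 signals centred on each gene's mean. Scores and genes below the filter were compared by two-sided exact permutation tests over all splits of the arrays. Correlations of fold changes were set beside 100 simulations of unchanged groups with the same controls, and beside 35 splits of the controls.

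Named genes followed a rule fixed in advance. For each dose against controls it takes the 10 largest rises and the 10 largest falls among genes past the threshold, filled up to 5 per direction by the smallest p. It adds Cyp1a1, Cyp1b1, Cyp1a2, Ahrr, Nqo1, Tiparp, Ahr, Nppa, Nppb, Myh6 and Myh7, and up to 4 genes per list by the smallest p. For the dose contrasts and the trend it takes the 5 smallest p in each direction. Of the list genes, examples are printed.

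The fits were tested on simulated data with the means and spreads of these arrays, in which 200 of 8097 probe sets were changed. At 2-fold, limma recovered 89% of them at 1.5 µg/kg, 92% at 3 µg/kg and 92.5% at 6 µg/kg. At 1.5-fold it recovered 49%, 61.5% and 58%. The control contrast recovered 82% at 2-fold. Without any change it called 0 at each dose. A list of 15 genes shifted by 1.2-fold passed at each dose and 0 of the other lists did. The simulated noise was independent between probe sets and between arrays. These rates therefore do not cover genes or arrays that move together, as they can in the real data.

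Alternatives planned in advance were quantile normalization, the signals as deposited, pseudocounts of 1 and 100, no filter, a filter at the 60th percentile, either set of 4 controls alone, the replicate number as a block, the largest residual component as a covariate, the 3′ to 5′ ratio of control probe sets as a covariate, no intensity trend, array weights, a minimum change of 1.5-fold, only the groups compared, log2(dose + 1), the TCDD doses alone, the mean of all probe sets of a gene for the lists, and leaving out each array. Chosen after seeing the data were leaving out 4 arrays by the β-actin 3′ to middle ratio, the lung epithelial score as a covariate, the Xist signal as a covariate and, for the lists, the probe set of each gene that is brightest in controls. The 4 arrays (controls 1, 2 and 6 and array 4 of 6 µg/kg) had log2 ratios of 0.896 or more and all others 0.61 or less. A further alternative that picked arrays by a measured component was run and dropped, because it would have grouped arrays by their outcome. Plots were drawn with matplotlib 3.10.9 in Python 3.11.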

Results

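Transcript levels were measured in whole hearts of fetal mice whose dams had received the dioxin TCDD, a ligand of the aryl hydrocarbon receptor (AhR), or corn oil alone by oral gavage on gestation day 14.5. Hearts were collected on day 17.5. The series holds 20 arrays: 8 controls and 4 at each of 1.5, 3 and 6 µg/kg. Its title names a dose response, so each dose was set against the controls, the doses were set against each other, and a linear trend over dose was fitted. The labels do not say whether an array holds 1 heart, a pool or a separate litter, so every p measures only the spread between these arrays. Each array's median signal lay between 171 and 211, and correlations between arrays lay between 0.941 and 0.981 across probe sets. The number of arrays limits the precision.

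The clearest response to TCDD was a rise of Cyp1a1 and Cyp1b1, the cytochrome P450 enzymes that are textbook targets of AhR. Cyp1a1 (chromosome 9, 57687928 to 57703824 of assembly GRCm38.p6) gave a mean signal of 39.6 ± 23.0 (SD, n = 8) in controls, 224 ± 134 (SD, n = 4) at 1.5 µg/kg, 275 ± 90.3 (SD, n = 4) at 3 µg/kg and 507 ± 150 (SD, n = 4) at 6 µg/kg. Its log2 fold changes were 1.76, 2.12 and 2.93, each with a standard error of 0.28 at a pseudocount of 32. The control signal is far below the array medians, so these sizes depend on the pseudocount: they were 1.15, 1.41 and 2.10 with 100 and 2.50, 2.93 and 3.82 with 1, and passed each time. Cyp1b1 gave 79.1 ± 19.4 (SD, n = 8) in controls and 422 ± 65.7 (SD, n = 4) at 6 µg/kg. Its log2 fold changes were 1.39, 1.45 and 2.04, each with a standard error of 0.17. Every TCDD array exceeded every control for both genes. The limma adjusted p from low to high dose was 0.00681, 0.000573 and 1.97e-06 for Cyp1a1, and 0.000174, 8.24e-05 and 1.49e-07 for Cyp1b1. Against controls 1 to 4 alone, Cyp1a1 had an adjusted p of 0.0573 at 1.5 µg/kg. In all, 2 of 18 alternatives ended that call (highest limma adjusted p 0.0881). A further Cyp1a1 feature, with a control signal of 94.5, did not pass at any dose (log2 fold changes −0.13, −0.44 and 0.18).

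**Figure D1:**
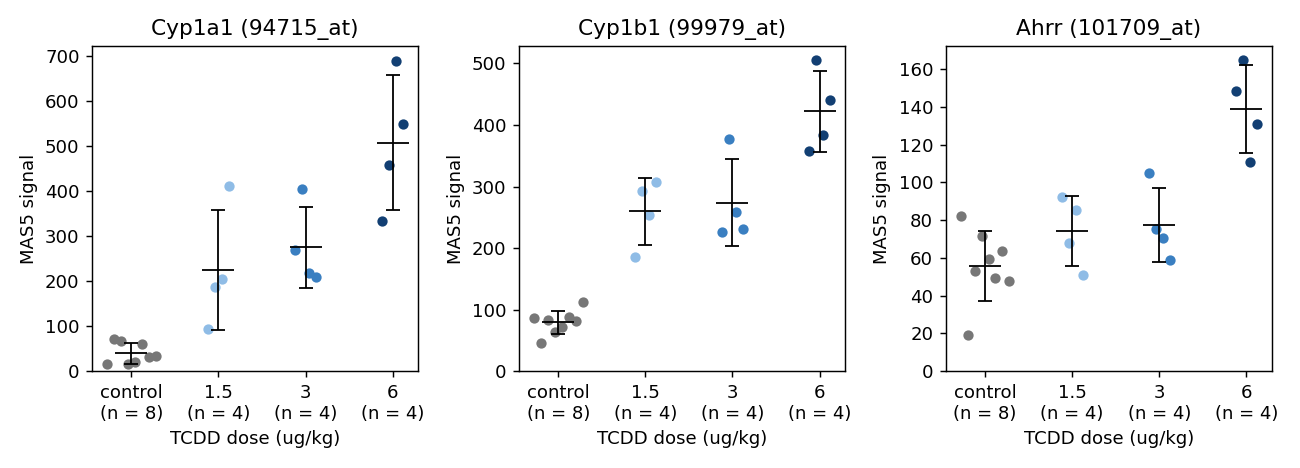
MAS5 signal per array (points) with mean and SD (bars) by TCDD dose for Cyp1a1, Cyp1b1 and Ahrr. The mean Cyp1a1 signal goes from 39.6 in controls to 507 at 6 µg/kg, and all 4 Ahrr values at 6 µg/kg lie above the 8 controls.

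Ahrr, which encodes the repressor of AhR, lay below the intensity filter and was tested separately. Its mean signal was 55.7 ± 18.7 (SD, n = 8) in controls and 139 ± 23.3 (SD, n = 4) at 6 µg/kg, near background, so no fold change is given. All 4 arrays exceeded the 8 controls (two-sided exact permutation p = 0.00202, the smallest that 495 splits allow; adjusted p = 0.0121 over 6 tests). At 1.5 and 3 µg/kg Ahrr averaged 74.0 and 77.4 (exact permutation p = 0.18 and 0.119). Cyp1a2, a hepatic relative of Cyp1a1, averaged 43.1 in controls and 56.5 at 6 µg/kg (exact permutation p = 0.317). Nqo1 and Tiparp, further AhR targets, and Ahr itself did not pass at any dose. Their log2 changes at 6 µg/kg were 0.17, 0.21 and −0.17. At 1.5 µg/kg Tiparp was at 0.04, and at −0.01 with quantile normalization.

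The AhR target list passed camera at each dose with the brightest probe set per gene over all arrays, carried by Cyp1a1 and Cyp1b1: its mean log2 change at 1.5 µg/kg was 0.54 and its median 0.19. Of its 7 measured genes, 6, 6 and 7 lay above controls, and Cyp1a1 and Cyp1b1 were the 2 that passed, both over all genes and adjusted over the list alone. The limma camera adjusted p was 0.00166, 1.79e-05 and 6.62e-09. With an estimated correlation the call at 1.5 µg/kg was lost (adjusted p = 0.0833), and the list passed with 0.0188 at 3 µg/kg and 0.00139 at 6 µg/kg. For Cyp1a1 that probe set is the brightest only because of the TCDD arrays. With the brightest in controls, chosen after the values were seen, the list did not pass at 1.5 and 3 µg/kg (adjusted p = 0.0841 and 0.0547) and passed at 6 µg/kg (9.51e-05).

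At 1.5 µg/kg, 16 probe sets rose and 1 fell against controls. Beside Cyp1a1 and Cyp1b1, the largest rises were Sh3bgr, an SH3-binding glutamate-rich protein of heart and muscle (log2 1.06 ± 0.16, SE), Cryl1, a crystallin-like dehydrogenase (1.01 ± 0.20), and Mtf2, a partner of the Polycomb complex (0.89 ± 0.15). Hspg2, the basement membrane proteoglycan perlecan, and Pias3, a SUMO ligase, both rose by 0.83. Jup, the junctional protein plakoglobin, rose by 0.79, the mRNA export factor Rae1 by 0.74, and Cd74, the MHC class II invariant chain of antigen-presenting cells, by 0.73 (SE 0.14). Cma1, the mast cell chymase, went from a signal of 453 ± 86.5 (SD, n = 8) to 227 ± 33.7 (SD, n = 4), so that it fell by 0.89 on the log2 scale. All 4 arrays lay outside the control range for each of these 9 genes. Below the threshold, the smallest p among lower genes belonged to Aimp1, Upp1, Polr3k and Hspe1 (log2 −0.41, −0.65, −0.61 and −0.36).

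The limma test gave 17 changed probe sets of 8097 at 1.5 µg/kg (adjusted p under 0.05), and 1021 had an unadjusted p under 0.05 where chance gives 405. Not all features of a gene moved together: the far brighter of the Sh3bgr probe sets was at −0.18, and further features stood at 0.28 for Cryl1, 0.03 for Mtf2, 0.05 for Rae1, 0.18 and 0.05 for Pias3 and 0.02 for Upp1, none of which passed. The count was 3 against controls 1 to 4 alone and 153 against controls 5 to 8 alone. Against controls 1 to 4 the calls of Cryl1 (0.0573), Mtf2 (0.0836), Rae1 (0.0848), Jup (0.0871), Pias3 (0.123), Cd74 (0.176) and Hspg2 (0.181) ended beside that of Cyp1a1, and against controls 5 to 8 those of Cma1 (0.0506) and Jup (0.0634). The count was 30 without the 4 arrays of high β-actin 3′ to middle ratio, 4 without array 1 or 2 of the dose and 51 without array 3. Of the named genes Cyp1a1, Cyp1b1 and Sh3bgr passed whichever array was left out. Mtf2 did not without array 1 (adjusted p = 0.0517), nor Pias3 without array 1 or 2 (0.122 and 0.156), nor Cma1 without array 1, 2 or 4 (0.0504, 0.156 and 0.0514). Without control 6 or without array 1 or 2 of the dose, Rae1 had 0.0548, 0.0517 and 0.24 and Cd74 had 0.0548, 0.064 and 0.249. Cryl1 was over 0.05 without controls 3 or 6 or arrays 1 or 2 (0.059 to 0.303), and Hspg2 without controls 3, 5, 6 or 7 or arrays 1 or 2 (0.0521 to 0.311). Jup was over it without controls 1, 2, 3, 5, 6 or 7, arrays 1 or 2 of the dose, arrays 2 or 4 of 3 µg/kg, or array 2 of 6 µg/kg (0.0501 to 0.249). In the other direction, Aimp1, Upp1 and Hspe1 passed without some arrays. These were control 8 or array 3 for Aimp1 (0.0386 and 0.0402), array 3 or 4 for Upp1 (0.0484 and 0.0385), and control 2 or array 4 for Hspe1 (0.0372 and 0.0416).

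Among the gene lists fixed before the data were examined, leukocyte markers were higher and fatty acid oxidation genes lower at 1.5 µg/kg. All 15 measured macrophage and leukocyte genes lay above controls, among them the complement components C1qc (log2 0.39) and C1qa (0.31) and the neutrophil alarmin S100a8 (0.50). Most of these genes are dim: 5 of the 15 lay above the median control signal of the kept probe sets. Ptprc, H2-Aa and H2-Ab1 lay below the filter and are not among them. None of the 15 passed over all genes and 3 passed adjusted over the list alone. The camera adjusted p was 6.39e-05, and adjusted p = 0.0218 with an estimated correlation. Of 23 fatty acid oxidation genes 18 were lower, with 0 passing over all genes by limma and 5 lower adjusted over the list alone. Examples are the fatty acid translocase Cd36 (−0.64), the mitochondrial reductase Decr1 (−0.41), the heart fatty acid carrier Fabp3 (−0.47) and the thioesterase Acot1 (−0.37). Camera gave an adjusted p of 5.29e-05, and adjusted p = 0.0402 with an estimated correlation. Brown fat markers, which share Fabp4 and Ppargc1a with that list, were lower in 5 of 7, 3 of them adjusted over the list alone by limma, with a camera adjusted p of 0.0520.

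A further 5 lists passed camera at 1.5 µg/kg and lost their call with an estimated correlation. Oxidative phosphorylation and TCA cycle genes were lower in 47 of 54 (Ndufv2 −0.22, Atp5k −0.33, Cox8b −0.35), with an adjusted p of 1.78e-07 but adjusted p = 0.349 with an estimated correlation. Structural matrix genes were higher in 38 of 47 (Hspg2 0.83, Col6a2 0.55, the elastin gene Eln 0.54, Tnxb 0.69), with 0.000126 but adjusted p = 0.349 with an estimated correlation. Hspg2 alone passed over all genes, and 2 passed adjusted over the list alone. Tnxb was at 0.28 against controls 1 to 4 and 1.09 against controls 5 to 8. Without array 3 of the dose Col6a2 passed as well (0.0402). Cardiac transcription factors were higher in 12 of 17 (Hand1 0.71, Hand2 0.47, Mef2a 0.48, Tbx2 0.47), 3 of them adjusted over the list alone, with 0.0167 but adjusted p = 0.349 with an estimated correlation. Mef2a differs between the control sets and was at 0.16 against controls 1 to 4 and 0.81 against controls 5 to 8. Without array 1 that list had 0.0597. G2/M genes were lower in 26 of 34 (Cdc20 −0.27, Smc4 −0.26), with 0.017 but adjusted p = 0.454 with an estimated correlation. Smc4 was at −0.05 with the 3′ to 5′ control ratio as a covariate. That call ended without controls 1 or 6 or array 3 (0.0866, 0.0557 and 0.0782). Glycolysis genes were lower in 13 of 18, with 0.0227 but adjusted p = 0.454 with an estimated correlation. That call ended without control 4 or arrays 1 or 3 (0.075, 0.0816 and 0.0732).

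At 3 µg/kg only Cyp1a1 and Cyp1b1 passed over all genes; both rose. The next smallest p among higher genes belonged to the thromboxane receptor gene Tbxa2r (log2 1.03 ± 0.21, SE; adjusted p = 0.144 by limma), Cd74 (0.61; 0.301) and the transcription factor gene Klf5 (0.79; 0.326). Among lower genes it belonged to Cma1 (−0.80 ± 0.16; 0.144), Aimp1 (−0.42), Lima1 (−0.41), Abhd8 (−0.45) and Dnaaf5 (−1.26), of which Abhd8 and Dnaaf5 have further features at −0.04 and −0.03. Every array at 3 µg/kg exceeded every control for Tbxa2r, and 3 of 4 lay below every control for Cma1. The limma count of 2 stood beside 463 probe sets with an unadjusted p under 0.05 where chance gives 405. It was 4 against controls 1 to 4 alone, 30 against controls 5 to 8 alone and 6 without the 4 arrays of high β-actin ratio. Tbxa2r passed without array 4 of 6 µg/kg (adjusted p = 0.00305) and Cma1 without control 8 (0.0305).

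The gene lists at 3 µg/kg again led with leukocyte markers, higher in 15 of 15 genes (C1qa 0.39, Tyrobp 0.38, C1qc 0.36, S100a9 0.63). None passed over all genes and 5 passed adjusted over the list alone. The camera adjusted p was 1.25e-09, and adjusted p = 0.000462 with an estimated correlation. Mitotic genes were lower in 30 of 34, among them the condensin gene Smc4 (−0.37), the kinesin gene Kif2c (−0.34), the checkpoint kinase gene Ttk (−0.34) and Cks2 (−0.20). Camera gave 7.77e-09, but adjusted p = 0.0608 with an estimated correlation. Oxidative phosphorylation genes were lower in 49 of 54 (Atp5a1 −0.14, Ndufs1 −0.19), with 4.01e-07 but adjusted p = 0.274 with an estimated correlation. Fatty acid oxidation genes were lower in 18 of 23 (Decr1 −0.28, Hadhb −0.24), with 0.00137 but adjusted p = 0.1 with an estimated correlation. Over the alternatives Ndufs1 ranged from −0.25 to −0.07 and Hadhb from −0.30 to −0.09. Structural matrix genes were higher in 37 of 47 (Bgn 0.39, Hspg2 0.51, Tnxb 0.67, Mfap2 0.30), with 2.6e-05 but adjusted p = 0.254 with an estimated correlation. Tnxb was at 0.27 against controls 1 to 4 and 1.08 against controls 5 to 8. Of these 4 lists, 1 matrix gene passed adjusted over the list alone.

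The remaining lists that passed camera at 3 µg/kg lost their call with an estimated correlation, and 0 of their genes passed in limma, over all genes or adjusted over the list alone. Retinoid signalling genes were higher in 8 of 8 (the retinoic acid synthases Aldh1a1 0.70 and Aldh1a2 0.56), with 0.00233 but adjusted p = 0.154 with an estimated correlation. Over the alternatives Aldh1a1 ranged from 0.15 to 0.77. Fibroblast and epicardial genes were higher in 14 of 16 (Tcf21 0.20), with 0.00233 but adjusted p = 0.165 with an estimated correlation. Contractile genes were lower in 19 of 26 (Ankrd1 −0.18), with 0.00766 but adjusted p = 0.302 with an estimated correlation. Glycolysis genes were lower in 14 of 18 (Pgk1 −0.21), with 0.0165 but adjusted p = 0.384 with an estimated correlation. Lung epithelial genes were higher in 9 of 9 (Scgb1a1 1.35, Sftpb 1.23), with 0.00303 but adjusted p = 0.302 with an estimated correlation. Array 1 of the dose stood apart, with a lung score of −0.59 where the others had 0.67 to 0.78. Without array 2 of the dose the adjusted p was 0.121 for fibroblasts, 0.071 for contractile genes, 0.121 for glycolysis and 0.0726 for lung. Without control 4 it was 0.0674 for contractile genes and 0.0962 for glycolysis. The mesothelial gene Msln, in a whole-heart sample, was at 0.32 and did not pass.

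At 6 µg/kg, Cyp1a1, Cyp1b1, Cd74 and Plac8 rose and Cma1 and Ints9 fell. Cd74 went from a signal of 133 ± 22.9 (SD, n = 8) to 278 (n = 4), a log2 rise of 0.92 ± 0.14 (SE; limma adjusted p = 0.00285). The control signal of Cd74 lies below the array medians, and over 17 alternatives its rise ranged from 0.70 to 1.07. Of these alternatives, 1 ended the call (0.0779). Plac8, a gene of leukocytes and placenta, rose by 0.79 ± 0.15 (0.0335). Cma1 went from 453 to 194 and fell by 1.09 ± 0.16 (0.00263), and Ints9, a subunit of the Integrator complex, fell by 1.22 ± 0.22 (0.0166). Its signal at 6 µg/kg, 53.0 ± 35.2 (SD, n = 4), is near background, and the fall was 0.77 with a pseudocount of 100 and 1.74 with 1. All 4 arrays lay outside the control range for each of these. Just short of the threshold were S100a8 (0.79; 0.0855) and the replication helicase gene Mcm7 (−0.39; 0.0804), followed by Celf1 (−1.21; 0.151) and Eps15l1 (−0.97; 0.151). These 2 were at −0.79 and −0.63 with a pseudocount of 100 and −1.65 and −1.31 with 1.

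The limma count of 6 at 6 µg/kg (4 higher, 2 lower) stood beside 741 with an unadjusted p under 0.05. It was 187 against controls 1 to 4 alone and 3 against controls 5 to 8 alone, where Plac8, Ints9 and Cma1 were at 0.66, −0.94 and −0.96 (adjusted p = 0.565, 0.446 and 0.186). It was 3 without the 4 arrays of high β-actin ratio and 12 without array 4 of the dose. Ints9 did not pass without array 3 or 4 (0.182 and 0.0569). Plac8 did not without controls 1, 2, 3, 4, 7 or 8, array 4 of 1.5 µg/kg, or arrays 2, 3 or 4 of the dose (0.0524 to 0.153). Conversely S100a8 passed without control 2 or 8 (0.0269 and 0.0185), Mcm7 and S100a9 without control 8 (0.0185 and 0.042), Celf1 without array 1 (0.00403) and Eps15l1 without array 4 of 3 µg/kg (0.0194).

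**Figure D2:**
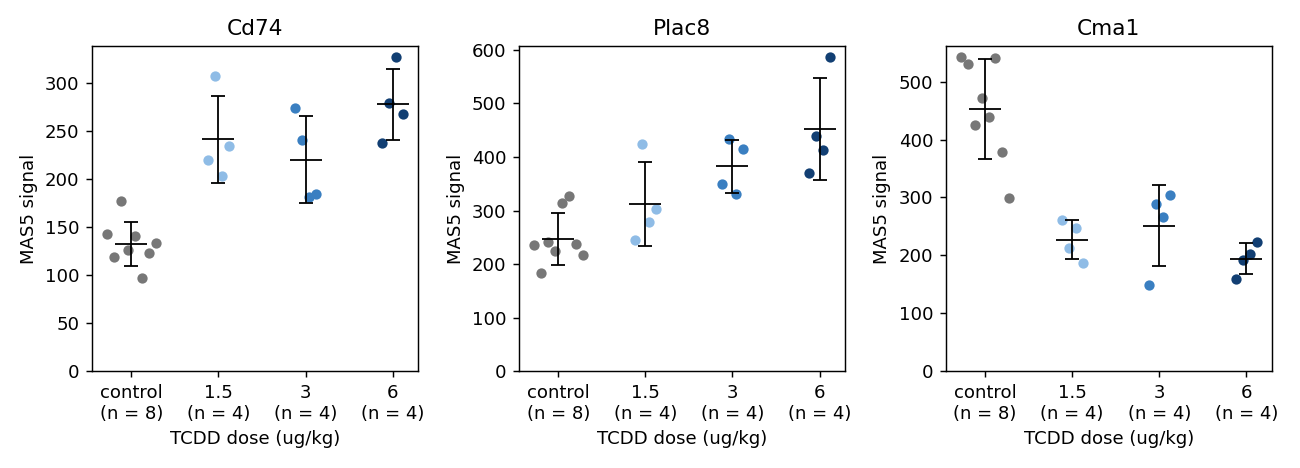
MAS5 signal per array (points) with mean and SD (bars) by TCDD dose for Cd74, Plac8 and Cma1. Cd74 averages 133 in controls and 278 at 6 µg/kg, and Cma1 averages 453 in controls and 194 at 6 µg/kg.

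Leukocyte markers showed their largest difference at 6 µg/kg, where all 15 genes lay above controls. The lysosomal protease gene Ctss was at 0.47, C1qa at 0.44, S100a8 at 0.79 and S100a9, which is dim in controls, at 0.89 (0.64 to 1.09 over the alternatives). None passed over all genes and 8 passed adjusted over the list alone. The camera adjusted p was 2.12e-10, and adjusted p = 0.000296 with an estimated correlation. The mean centred log2 signal of the list was higher than in controls by 0.25, 0.29 and 0.35 from low to high dose. At each dose all 4 arrays exceeded the 8 controls (two-sided exact permutation p = 0.00202, the smallest possible; adjusted p = 0.0182 over 27 such tests). Liver markers, which fetal blood-forming tissue can bring, were higher on average by 0.31, 0.19 and 0.32 in 7, 7 and 8 of 9 genes, with camera adjusted p of 0.171, 0.345 and 0.0871. This difference rests on controls 1 to 4, where the liver score lay between −0.81 and −0.41. It lay between −0.17 and 0.50 in controls 5 to 8, which the TCDD arrays overlapped (−0.40 to 0.91, the highest in array 3 of 1.5 µg/kg). The same score of 12 erythroid genes was higher by 0.16, 0.07 and 0.07 (exact permutation p = 0.291, 0.566 and 0.61), and that of 9 lung epithelial genes by 0.28, 0.58 and 0.09 (exact permutation p = 0.352, 0.107 and 0.762). Lung epithelial transcripts differed widely between arrays of 1 group: the surfactant gene Sftpc ranged from 128 to 2333 among controls.

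**Figure D3:**
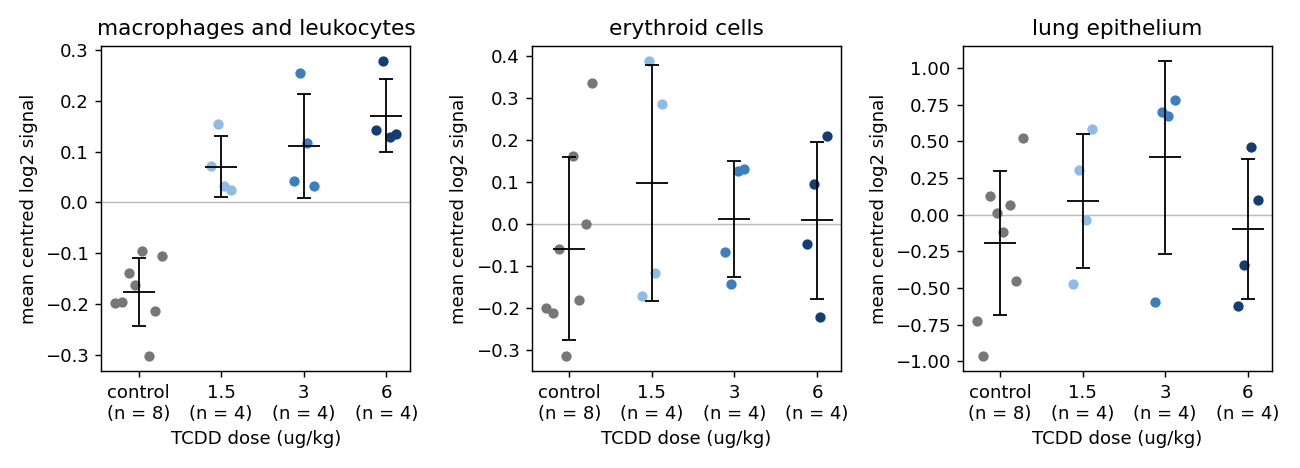
Mean centred log2 signal of 3 marker lists per array (points) with mean and SD (bars) by TCDD dose. All TCDD arrays lie above all controls for leukocyte markers, and the groups overlap for erythroid and lung epithelial markers.

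Cell cycle genes were also lower at 6 µg/kg. Of 34 mitotic genes 29 were lower (Mad2l1 −0.34, Anln −0.34, Plk1 −0.38 with further features at 0.17 and 0.21, Cdc20 −0.27), 1 of them adjusted over the list alone, with a camera adjusted p of 0.000395 but adjusted p = 0.541 with an estimated correlation. Of 33 G1/S genes 25 were lower (Cdc45 −0.40, against the licensing inhibitor Gmnn at 0.31), 1 of them adjusted over the list alone, with 0.0216 but adjusted p = 0.622 with an estimated correlation. Cdc45 was at −0.64 against controls 1 to 4, −0.16 against controls 5 to 8 and −0.15 without the 4 arrays of high β-actin ratio. The G1/S call ended in 7 of 18 alternatives (adjusted p up to 0.664 by camera or fry), among them the mean of all probe sets of a gene (0.136). It also ended without control 6 or arrays 1, 2 or 4 of the dose (0.0824, 0.106, 0.0777 and 0.0793). The G1/S score per array lay between 0.084 and 0.118 in controls 1 to 4 and was 0.104 in control 6. In controls 5, 7 and 8 it was −0.090, −0.069 and −0.085, within the range of 6 µg/kg (−0.093 to 0.012). The score of the mitotic genes was highest in controls 1, 2 and 6, which have the high β-actin ratio (0.192, 0.123 and 0.149). In the other controls it lay between −0.023 and 0.037, and at 6 µg/kg between −0.100 and 0.055. Of the lists that had moved at lower doses, some did not pass here: matrix structure gave 0.958, fatty acid oxidation 0.307 and oxidative phosphorylation 0.307. Whether these differ from the lower doses was not tested. Without control 6 or array 2 of the dose, oxidative phosphorylation genes passed as higher (0.0291 and 0.0166).

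**Figure D4:**
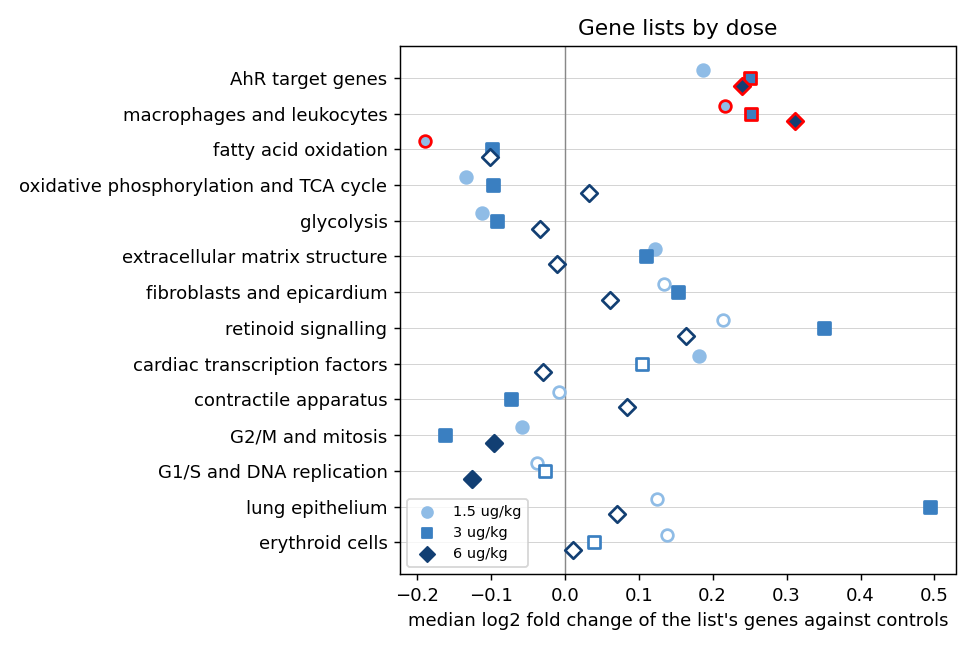
Median log2 fold change against controls (x axis) of the measured genes of 14 lists at 1.5, 3 and 6 µg/kg. Filled symbols passed camera, and red outlines mark lists that also passed with an estimated correlation. The leukocyte list lies at 0.22, 0.25 and 0.31.

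The cardiac genes named in advance did not pass at any dose. Myh6, the α-myosin heavy chain, averaged 15500 in controls and was at log2 −0.23, −0.22 and −0.07. Myh7, the β isoform, was at 0.04, −0.09 and 0.10, with its sign turned at 3 and 6 µg/kg under quantile normalization (0.01 and −0.03). The natriuretic peptide genes Nppa (−0.05, 0.00 and −0.04) and Nppb (−0.25, −0.11 and 0.08) did not pass either.

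Set against each other, 1.5 and 3 µg/kg did not differ in any probe set by limma, with 226 at an unadjusted p under 0.05. Cyp1a1 and Cyp1b1 did not differ between doses past the threshold: the differences were 0.36 and 0.06 for 3 against 1.5 µg/kg (adjusted p = 0.9999 for both), 0.81 and 0.59 for 6 against 3 µg/kg (0.343 and 0.248) and 1.17 and 0.65 for 6 against 1.5 µg/kg (0.0919 and 0.107). The smallest p for 3 against 1.5 µg/kg belonged to Sh3bgr (−0.81), Rae1 (−0.71), Mtf2 (−0.67), Clcn7 (−0.38) and Lgi4 (−1.47) among genes lower at 3 µg/kg. Among higher genes it belonged to Rcan3 (1.14), Rnasek (0.35), Mrpl13 (0.33), Trir (0.30) and Smap1 (0.44). At 6 against 3 µg/kg, the ankyrin gene Ank3 fell by 1.23, the RNA-binding protein gene Igf2bp1 by 1.05 and Ints9 by 1.41, each with a limma adjusted p of 0.0282, and 943 probe sets had an unadjusted p under 0.05. Klf5 (−1.14; 0.0512), Kcnj5 (−1.21), Pam (1.22), Ctrl (1.24), Ccar1 (0.61), Ino80c (0.58) and the chaperonin gene Hspe1 (0.41) did not pass. At 6 against 1.5 µg/kg, 4 probe sets rose and 24 fell, with 1262 at an unadjusted p under 0.05. Igf2bp1 fell by 1.21, Ints9 by 1.56, Ank3 by 1.31, Mtf2 by 0.95 and the nucleoside transporter gene Slc29a2 by 1.39. Hspe1 rose by 0.53, the peptide amidase gene Pam by 1.31, the ATP synthase gene Atp5l by 1.04 and the integrin gene Itgav by 1.86, while Fdps (0.64; 0.0509) did not pass. Ints9 at 6 µg/kg and Itgav at 1.5 µg/kg (mean signal 66.5) are near background, so their sizes depend on the pseudocount: from 1 to 100 Ints9 fell by 1.97 to 0.90 against 3 µg/kg and by 2.15 to 1.02 against 1.5 µg/kg, and Itgav rose by 2.36 to 1.32 (adjusted p = 0.0528 with 1). Further features of 3 of these genes did not pass at any dose: against controls Ank3 was at 0.08 at 3 µg/kg and 0.05 at 6 µg/kg, and at 1.5 and 6 µg/kg Itgav was at 0.09 and −0.01 and Atp5l at −0.11 and −0.05.

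These counts rest on single arrays and on how the arrays group. The 3 calls of 6 against 3 µg/kg became 0 without any 1 array of 3 µg/kg or array 2 or 3 of 6 µg/kg, and 6 without array 4 of 6 µg/kg. Ank3, Igf2bp1 and Ints9 each lost their call there without any 1 of the 4 arrays of 3 µg/kg (0.0547 to 0.0968), or without array 2 or 3 of 6 µg/kg (0.0991 to 0.196). Ank3 and Igf2bp1 also lost it without array 1 of 6 µg/kg (0.0936), and Ints9 without array 4 (0.0651) or with a pseudocount of 100 (0.0558). Klf5 passed without controls 3 or 7 or arrays 2 or 3 of 1.5 µg/kg (0.0218 to 0.0496). The 28 calls of 6 against 1.5 µg/kg became 2 without array 2 of either dose, 71 without control 6 and 137 without the 4 arrays of high β-actin ratio. Igf2bp1 and Ints9 kept their calls whichever array was left out. Ank3 lost its call without array 2 of either dose (0.0506 and 0.0537), as did Mtf2 (0.0541 and 0.0537), which also did without array 1 of 1.5 µg/kg (0.108). Slc29a2 did so without arrays 1 or 2 of 1.5 µg/kg or 2 or 3 of 6 µg/kg (0.0541 to 0.108). Hspe1 and Pam did so without arrays 1, 2 or 3 of 1.5 µg/kg or 2 or 3 of 6 µg/kg (0.0517 to 0.108), Hspe1 also without array 1 of 6 µg/kg (0.0534) and Pam without array 4 (0.0522). Atp5l did so without any 1 array of 1.5 µg/kg or arrays 1, 2 or 3 of 6 µg/kg (0.0554 to 0.112). Itgav did so without arrays 1, 2 or 3 of 1.5 µg/kg, 1 or 2 of 3 µg/kg or any 1 of 6 µg/kg (0.0516 to 0.139). Fdps passed without controls 1, 2, 3, 5 or 6 or array 4 of 3 µg/kg (0.0151 to 0.0492).

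A linear trend over dose passed for Cyp1a1 (0.49 log2 units per µg/kg), Cyp1b1 (0.33), Cd74 (0.15) and Plac8 (0.14), which rose, and for Cma1, which fell by 0.18 per µg/kg. The limma adjusted p was 8.23e-05 for both cytochromes, 0.0244 for Plac8 and 0.0396 for Cd74 and Cma1. Over the TCDD doses without controls the slopes were 0.26 and 0.15 for the cytochromes, which passed narrowly (0.0473 and 0.0483). They were 0.10 for Plac8 (0.137), 0.05 for Cd74 (0.492) and −0.05 for Cma1 (0.55), which did not pass. That fit called 219 probe sets. A difference of 6 µg/kg from the lower doses cannot be told apart there from a batch. Each of these slopes was smaller than with controls, so the trends, those of the cytochromes included, rest in part on the step from controls to TCDD. With controls 5 to 8 alone the slopes of Plac8, Cd74 and Cma1 were 0.11, 0.14 and −0.13, which did not pass (0.65, 0.65 and 0.871). Ctss (0.08), Celf1 (−0.19), Eps15l1 (−0.16), Foxk2 (−0.07) and Mcm7 (−0.06) did not pass. The unadjusted count was 585. The count was 2 to 6 when 1 array was left out, and both cytochromes passed each time. Plac8 lost its call without controls 1, 2, 3, 4 or 7 or arrays 2 or 4 of 6 µg/kg (0.0521 to 0.0992). Cd74 lost it without any 1 control, array 3 of 1.5 µg/kg, arrays 1, 2 or 3 of 3 µg/kg or arrays 2, 3 or 4 of 6 µg/kg (0.0514 to 0.217). Cma1 lost it without controls 1 to 7, arrays 2 or 3 of 3 µg/kg or any 1 array of 6 µg/kg (0.0594 to 0.132). Ctss passed without array 4 of 3 µg/kg (0.0411) and Celf1 without array 1 of 6 µg/kg (0.0138). The trend passed for 165 probe sets with controls 1 to 4 alone and 2 with controls 5 to 8 alone, and for 2 without the 4 arrays of high β-actin ratio. A joint test of the 3 doses called 15 probe sets of 1011 at an unadjusted p under 0.05. It called 8 without array 1 or 2 of 1.5 µg/kg, 36 without control 4 and 99 without the 4 arrays of high β-actin ratio.

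Across the 8097 probe sets, fold changes at 1.5 and 3 µg/kg correlated with r = 0.62, at 1.5 and 6 µg/kg with r = 0.17, and at 3 and 6 µg/kg with r = 0.19. Probe sets are not independent replicates, and the comparisons share their controls. Simulated groups without any change gave 0.33 for each pair. When each dose had its own 4 controls, the mean r over 35 splits was 0.28, −0.04 and −0.06, and for the first pair r ranged from 0.10 to 0.42. With the first dose of each pair on controls 1 to 4 and the other on controls 5 to 8 r was 0.17, 0.11 and 0.08, and the other way round 0.11, −0.30 and −0.33. The covariance was 0.0262, 0.00816 and 0.00777 against a simulated 0.0108, 0.0108 and 0.0107. The first pair alone exceeded the simulated value, but how far depends on which controls are used. The other pairs lay below it. A batch shared by 1.5 and 3 µg/kg could also raise the first pair. The labels give no batch, so this cannot be told apart from a shared response. Cyp1a1 and Cyp1b1 were called higher at all 3 doses. Shared higher calls numbered 2, 3 and 2; these counts share their controls and were not tested. Cma1 was the shared lower call of 1.5 and 6 µg/kg.

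**Figure D5:**
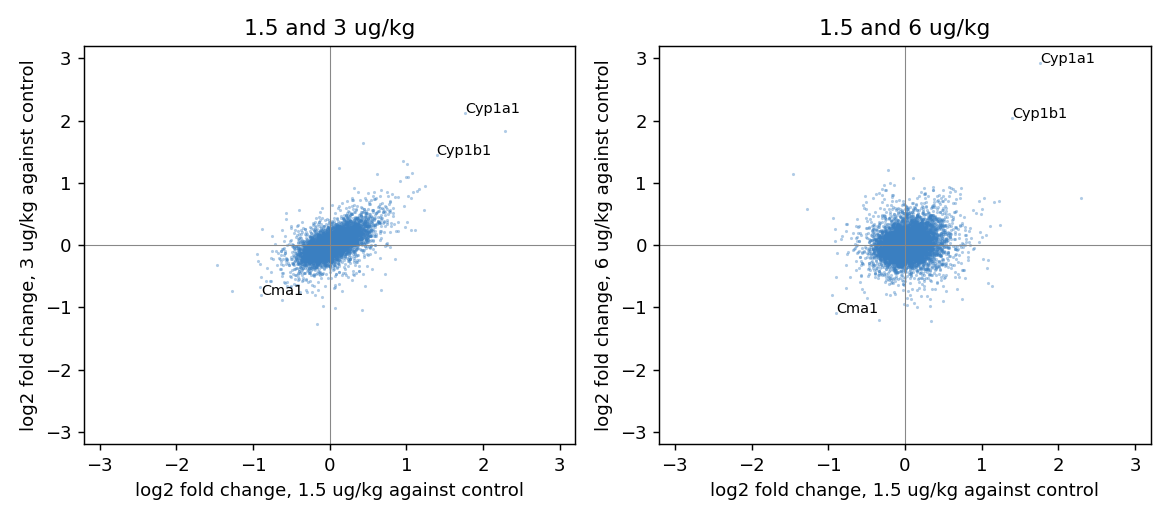
Log2 fold change of 8097 probe sets against controls at 1.5 µg/kg (x axis) and at 3 or 6 µg/kg (y axis); each point is a probe set. The correlation is 0.62 in the left panel and 0.17 in the right panel.

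The labels number 8 controls where the design text counts 4 arrays per group, so controls 1 to 4 were set against controls 5 to 8. Limma called 23 probe sets, 15 higher and 8 lower in controls 5 to 8, and 1129 had an unadjusted p under 0.05. The disulphide isomerase gene Pdia3 had a mean signal of 336 in controls 1 to 4 and 1280 in controls 5 to 8, a log2 difference of 1.83 ± 0.12 (SE; adjusted p = 2.48e-05). Genes chosen after their values were seen include the chaperone gene Dnajc7 (1.06), Crip2 (1.10) and Cdh13 (1.12), which were higher, and Mef2a (−0.66), which was lower in controls 5 to 8. The count was 3 without control 5 and 78 without control 6. Against controls 1 to 4, the doses of 1.5, 3 and 6 µg/kg gave 3, 4 and 187 changed probe sets. Against controls 5 to 8 they gave 153, 30 and 3. Cyp1b1 passed at every dose against either set. Ank3 and Igf2bp1 passed at 6 µg/kg against controls 1 to 4 (log2 −0.88 and −0.76) but were at −0.18 and −0.26 against controls 5 to 8 (adjusted p = 0.981 for both).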

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

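Every test of an explanation for the 3 patterns below was chosen only after the result it explains, or values close to it, had been seen. The bars for RNA quality, for mast cells and for Cma1 against the control sets were also changed once after their values were known, and under the earlier bars these 3 explanations stayed open. The prediction for blood was likewise reworded and split by dose after its value had been seen. Before that, blood had been tested at the highest dose alone, and the wording of the prediction did not match the rule that was run. The counts over other splits of the arrays were set before.

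Leukocyte markers lay higher in TCDD hearts at every dose. More blood in these hearts stays open at every dose. At 6 µg/kg the leukocyte score exceeded the erythroid score by 0.28 more than in controls. This goes against blood before adjustment only (two-sided exact permutation p = 0.0364, adjusted p = 0.0655 over 27 tests). At 1.5 and 3 µg/kg the value was 0.09 and 0.22 (exact permutation p = 0.493 and 0.117). The erythroid score lay between −0.316 and −0.060 in controls 1 to 4 and between −0.181 and 0.336 in controls 5 to 8. The blood test was not repeated against each set. Lung tissue carried along is argued against at 3 and 6 µg/kg, where the list passed camera with the lung score as a covariate (adjusted p = 0.00302 at most, with an estimated correlation), and cannot be told apart at 1.5 µg/kg (adjusted p = 0.0517, with the mean log2 change going from 0.25 to 0.24). A difference between the control sets is argued against, since the score was higher at each dose against each set, by 0.24 at least (exact permutation p = 0.0286 in all 6 comparisons, the smallest possible, and adjusted p = 0.0551). A graded effect of TCDD stays open, with a slope of 0.02 per µg/kg over the 12 TCDD arrays (permutation p = 0.0919), and because blood is not excluded, a real increase in leukocytes is not concluded.

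The arrays of 6 µg/kg stood apart from those of 1.5 and 3 µg/kg. Whether poor RNA in arrays with a high β-actin 3′ to middle ratio plays a part stays open. The β-actin 3′ to 5′ ratio did not set these arrays apart, so poor RNA in them is itself not shown. Its log2 value was 0.253, 0.401 and 0.310 in controls 1, 2 and 6 and 0.281 in array 4 of 6 µg/kg. The highest, 0.699, was in control 8. Array 4 of 6 µg/kg is the only TCDD array of high 3′ to middle ratio. Without it the 31 called differences of 6 against 1.5 or 3 µg/kg kept their direction at 0.991 (SD 0.0978) of their mean size, each above a bar of 0.667. These differences had been called with that array in the fit, so this test could hardly have come out otherwise. It shows only that their sizes do not rest on that array. A batch that 6 µg/kg shares with controls 5 to 8, and the lower doses with controls 1 to 4, is a candidate explanation: across probe sets the difference between 6 µg/kg and the lower doses correlated with that between the control sets at r = 0.42, the highest of 35 splits of the controls (next 0.40). Matched in this way, the doses gave 3, 4 and 3 changed probe sets, and with the sets exchanged 153, 30 and 187. The labels give no batch, so the part of the difference that is due to dose cannot be told apart from it.

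Cma1, the mast cell chymase, lay lower at every dose. The other measured mast cell genes of a list of 10 argue against fewer mast cells as the whole cause, without excluding it. Their median stayed above Cma1 by 0.71 at least, where their SD was 0.26 at most. This held over the 3 doses and with all 5 genes or without Kit and Gata2, which other cells also express. Cma1 was picked for its fall and the other genes were not, which can widen this gap. A smaller loss of mast cells stays open, since the 5 genes averaged −0.19 against controls at 6 µg/kg (two-sided exact permutation p = 0.0606; adjusted p = 0.0963), with Cpa3 at −0.46 and Tpsb2 at 0.05, and −0.11 and −0.08 at 1.5 and 3 µg/kg (exact p = 0.251 and 0.384). A difference between the control sets is argued against, since Cma1 was lower than each set at each dose, by −0.67 (SE 0.20) at the smallest, though 1 of the 6 exact permutation tests, at 3 µg/kg against controls 5 to 8, gave 0.0571 where the others were under 0.05. A lower level of this transcript alone may also hold and was not tested.

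Chance groupings of the arrays were counted by refitting other splits, 100 where more exist. The share of splits that gave as many, the real one included, was under 0.05 for the 17 changed probe sets of 1.5 µg/kg (2 of 100, highest other 93). It was also under 0.05 for the 2 of 3 µg/kg (3 of 100, highest other 3). These shares were not adjusted over the counts tested and 100 splits are a draw, so chance is made less likely but not excluded. They concern the counts, not single genes such as Cyp1a1 and Cyp1b1. The same holds for the 28 of 6 against 1.5 µg/kg (1 of 35, the smallest share possible, highest other 1) and the 15 of the joint test (1 of 100, highest other 1). It holds as well for the 5 of the trend (1 of 100, highest other 4) and the 23 between the control sets (1 of 35, highest other 1). No such test is possible for the 0 of 3 against 1.5 µg/kg, since every split reaches that count (highest other 7). The share was 0.05 or more for the 6 of 6 µg/kg (5 of 100, highest other 130) and the 3 of 6 against 3 µg/kg (2 of 35, highest other 3), so chance stays open there. It also stays open for the 8, 11 and 4 gene lists that moved at 1.5, 3 and 6 µg/kg. There 12, 6 and 43 of 100 splits gave as many (highest others 14, 13 and 10). Splits with 93 or 130 calls, several times the real counts, point to a structure among the arrays beyond the groups.

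Of 392 groups of values, 24 held an array far from the others, where chance gives about 20, which is 19.6. Array 4 of 6 µg/kg had Mtf2 at 227 (others 341 to 361), Jup at 709 (1255 to 1392), Tbxa2r at 315 (102 to 111) and Cd36 at 132 (168 to 172). Array 4 of 3 µg/kg had Tbxa2r at 277 (196 to 207) and Smc4 at 1856 (2292 to 2342). Array 1 of 3 µg/kg had Nqo1 at 121 (102 to 103), Atp5k at 664 (466 to 475) and Bgn at 5407 (6819 to 7077), and a lung score of −0.59 (0.67 to 0.78). Array 2 of 6 µg/kg had S100a8 at 458 (370 to 381) and a leukocyte score of 0.28 (0.13 to 0.14). Array 1 of 6 µg/kg had Bgn at 4488 (4908 to 4964), and array 3 had Sftpb at 540 (54.1 to 64.1). At 1.5 µg/kg, array 1 had Trir at 1464 (1619 to 1648), array 3 had Pam at 55.2 (129 to 147) and array 4 had Itgav at 132 (41.9 to 49.6). At 3 µg/kg, array 3 had Ino80c at 156 (113 to 119) and Itgav at 18.2 (137 to 166), and array 2 had Kcnj5 at 127 (204 to 221). Among controls, control 3 had Klf5 at 223 (99.5 to 139), control 7 had Eln at 9354 (12996 to 17433), and control 6 had 2 Fdps probe sets at 1226 (709 to 838) and 2406 (1055 to 1556). Ahrr, below the intensity filter, averaged 139 at 6 µg/kg where controls lay between 19.3 and 82.1.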

How the results depend on the processing

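Leaving out the 4 arrays of high β-actin ratio, the lung and Xist covariates and the brightest probe set in controls were chosen after seeing the data. Of 36 gene calls 14 kept their direction and their side of the threshold under every alternative other than leaving out single arrays, and of 23 list calls 5 did. The cause was not tested for any change given here unless it is named.

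The counts that moved by more than 1.5 times follow, beside 17, 2 and 6 at 1.5, 3 and 6 µg/kg, 28 for 6 against 1.5, 3 for 6 against 3, 0 for 3 against 1.5, 15 for the joint test, 5 for the trend and 23 between the control sets. With controls 1 to 4 only they were 3, 4 and 187, with 87 joint and 165 for the trend. With controls 5 to 8 only they were 153, 30 and 3, with 169 joint and 2 for the trend. With the largest residual component as a covariate they were 40, 5 and 18, 1 for 3 against 1.5, 25 for 6 against 3, 166 for 6 against 1.5, 85 joint and 10 for the trend. Without the 4 arrays they were 30, 6 and 3, 66 for 6 against 3, 137 for 6 against 1.5, 99 joint and 2 for the trend. With array weights they were 26, 4 and 10, 136 joint and 558 between the control sets. Without a filter, which tests more probe sets, they were 8 at 1.5 µg/kg, 0 for 6 against 3, 9 for 6 against 1.5, 2 for the trend and 12 between the control sets. With only the compared groups they were 8 at 1.5 µg/kg and 52 for 6 against 1.5. The 3′ to 5′ covariate gave 42 at 1.5 µg/kg. Quantile normalization gave 44 for 6 against 1.5. Between the control sets there were 44 with a pseudocount of 100, 45 with the 60th percentile and 11 without the intensity trend. The trend gave 219 over the TCDD doses only, 3 with the lung covariate and 2 with the Xist covariate, which gave 0 for 6 against 3.

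The numbers do not pair the arrays: over 24 pairs of the same number, residual correlations lay between −0.22 and 0.21. With the replicate number as a block the counts were 2 at 1.5 µg/kg, 133 at 6 µg/kg, 25 for 6 against 3, 98 for 6 against 1.5, 66 joint and 129 for the trend, and 13 lists moved at 1.5 µg/kg. Controls 5 to 8 have no partner and leave that fit. Fold changes at 6 µg/kg then correlated with those at 1.5 and 3 µg/kg at 0.46 and 0.53, as with controls 1 to 4 only (0.46 and 0.53). With controls 5 to 8 only the value for 1.5 and 6 µg/kg was 0.32.

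Of gene lists, 8, 11 and 4 moved at 1.5, 3 and 6 µg/kg. An estimated correlation left 2, 2 and 2, and fry 3, 3 and 2. Controls 5 to 8 only gave 5 and 7 at 1.5 and 3 µg/kg, the filter at the 60th percentile 2 at 6 µg/kg, and leaving out the 4 arrays 7 at 3 µg/kg.

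Directions reversed only for genes and lists that had not passed, and for lung epithelium at 3 µg/kg with its own score as a covariate (adjusted p = 0.862), which that covariate removes by construction. Quantile normalization turned Tiparp at 1.5 µg/kg (−0.00832) and Myh7 at 3 and 6 µg/kg (0.0143 and −0.0298). Controls 1 to 4 only and the block each turned Tiparp at 1.5 µg/kg (−0.0403 and −0.0403) and Nppa at 3 µg/kg (−0.0942 and −0.0942). Controls 5 to 8 only turned Nppa at 1.5 and 6 µg/kg (0.0462 and 0.0592). Nppa at 3 µg/kg was −0.0338 with the 3′ to 5′ covariate, −0.00365 with the lung covariate and −0.00498 with the Xist covariate. Nppb at 6 µg/kg was −0.0315 with array weights and −0.0140 without the 4 arrays. Without these, Ahr and Nppa at 1.5 µg/kg were −0.0668 and 0.0206 and Nppa at 6 µg/kg was 0.035. Ahr at 1.5 µg/kg was −0.0233 with the lung covariate. At 6 µg/kg the matrix list turned with adjusted p of 0.88 without a filter, 0.322 with controls 1 to 4 only, 0.329 with the block, 0.93 with fry, 0.729 without the 4 arrays and 0.92 with the Xist covariate. With controls 5 to 8 only and without the 4 arrays, the erythroid list turned (0.815 and 0.863), as did the lung list (0.895 and 0.357).

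When each array was left out in turn, the counts ranged from 4 to 51 at 1.5 µg/kg, 2 to 3 at 3 µg/kg, 4 to 12 at 6 µg/kg, 0 to 0 for 3 against 1.5, 0 to 6 for 6 against 3, 2 to 71 for 6 against 1.5, 8 to 36 for the joint test, 2 to 6 for the trend and 3 to 78 between the control sets. The lowest were without array 1 or 2 of 1.5 µg/kg (4 and 8), array 3 of 6 µg/kg (4), array 2 of 1.5 or 6 µg/kg (2 for 6 against 1.5) and control 5 (3). The highest were without array 3 of 1.5 µg/kg (51), array 4 of 6 µg/kg (12 and 6), control 6 (71 and 78) and control 4 (36). Lists moved numbered 6 to 12, 7 to 14 and 3 to 5, and correlations ranged from 0.53 to 0.65, 0.10 to 0.23 and 0.10 to 0.27. Results that crossed 0 were, at 1.5 µg/kg, Ahr (−0.0318 to 0.15), Myh7 (−0.0280 to 0.17), Nppa (−0.11 to 0.0107), Nqo1 (−0.16 to 0.0291) and Tiparp (−0.22 to 0.19), Nppa at 3 µg/kg (−0.0529 to 0.0306) and Nppa and Nppb at 6 µg/kg (−0.10 to 0.00771 and −0.12 to 0.19). At 6 µg/kg the adjusted p ranged from 0.59 to 0.983 for the matrix list and 0.0166 to 0.969 for oxidative phosphorylation.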

Other observations

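Endothelial and smooth muscle markers, further cell types of the heart, did not pass camera at any dose. Their adjusted p at 6 µg/kg was 0.307 for both lists, with 11 of 17 endothelial and 8 of 11 smooth muscle genes lower. The albumin gene Alb ranged from 118 to 2147 across the 20 arrays.

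The X-inactivation transcript Xist, which female cells express, ranged from a signal of 4.40 to 1601 across arrays, and from 4.40 to 1601 among controls alone. It was 34.1 or less in controls 1, 2 and 7 and in array 1 of 1.5 µg/kg. At 3 and 6 µg/kg it was at least 547 and 176, so it was not balanced between the groups. The Y-linked gene Uty was at 125 to 169 in those arrays of low Xist and at 35.8 to 139 in the others. Sftpc, the surfactant gene, ranged from 135 to 3512 at 3 µg/kg and from 134 to 2367 at 6 µg/kg.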
